A study of Danio rerio with 12 samples.

How the data were processed

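The series holds RNA profiles of cells sorted by fluorescence from dissociated whole zebrafish (Danio rerio) embryos and larvae that carried a transgene marking catecholaminergic cells, the neurons and related cells that make dopamine or noradrenaline. Each of 6 experiments gave 1 library of GFP-positive cells and 1 library of GFP-negative cells, 12 libraries in all. The 4 libraries at 24 h after fertilization were made from total RNA with NanoCAGE, which reads the capped 5′ ends of transcripts, and the 8 libraries at 36, 48, 72 and 96 h were made by mRNA sequencing of polyadenylated RNA after an amplification step, per the labels' protocols. Groups were taken from the sample titles. Each group has 1 library, so no group has replicates.

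The aligner and its version are not given in the sources used here, and the sheet names place the tables on the Zv9 genome build. Each of the 6 deposited tables lists the same 32312 features. Per the file headers of the vmat2 table, the authors deposited whole-number counts of total exon reads, of unique exon reads and of reads over the whole gene for both of its libraries. In the same deposited table the RPKM values equal total exon reads divided by exon length and by a library total. That total, worked out from the features, was 1916181 reads in the GFP-negative and 1494288 in the GFP-positive library, to within 1 read in all 14512 and 14995 features with a read. The exon length, chromosome, gene start and gene end come from the same table, per the file headers, and 4483 features have an exon length of 0 there. In every table the authors also deposited 2 comparison values per feature, a difference and a signed fold change between the 2 libraries' RPKM, recorded here with the unit score because neither has a fixed range. Where 1 library is at 0 the fold change is a fixed large number or infinite, depending on the table, with the sign giving the library, and any size of 10000 or more was read that way.

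Only the vmat2 table names its libraries in the headers. The other 5 tables give both libraries the same column names, so none of the 174 columns of library values for those 10 libraries was tied to a sample, and none was used. Their comparison columns were used instead. In the vmat2 table the deposited difference equals GFP-positive minus GFP-negative RPKM in all 32312 features, and the sheets of the other 5 tables carry the same GFP- against GFP+ heading, so the same direction was taken for them. If a table followed the opposite convention, every direction given for it would turn.

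The difference and the fold change together fix both RPKM levels, and a level times the exon length is a whole multiple of what 1 read is worth. Dividing by that unit gave the whole reads behind each comparison: to 1 decimal of a percent, all values above 0 lay within 0.02 of a whole number in each of the 12 libraries. In the vmat2 table the reads recovered this way equalled the deposited total exon reads in all 17237 features with a difference. Features with the same level in both libraries have a difference of 0, give no reads and were not considered.

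Within each experiment, read counts were brought to CPM (reads relative to library size) and scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with the GFP-negative library as the reference, and log2 ratios of GFP-positive over GFP-negative were taken with a prior count of 2. A gene was considered if its larger library held at least 5 CPM and 20 reads. In shallow pairs of unequal depth, 20 reads are reached at a lower CPM in the deeper library, so genes higher there are considered more readily. Scaling on total library size alone changed the log2 ratios of considered genes by a median of 0.59 in the vmat2 experiment, 0.41 in the otpb experiment, -0.74 at 36 h, 0.13 at 48 h, 0.21 at 72 h and 0.09 at 96 h. Single genes carry an exact (Clopper-Pearson) 95% interval for the ratio of their reads, with no prior count. Where 1 library had no read of a gene, the fold was computed against a floor of 3 reads in that library and is printed as at least that size. It leaves out the counting error of the other library, so the exact interval can reach lower. The 2 libraries of a pair are compared with each other, not the conditions they stand for, and no p-value was computed across genes. The median of a gene list with at least 3 considered members was placed among the medians of 10000 random lists of the same size, matched on mean expression, and is called set apart here where it lay outside their central 95%.

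The 22 gene lists, the rule for the genes named, the log2 ratios and their alternatives were fixed before the data were examined, except that reads recovered from the comparison columns took the place of library columns once the tables had been seen. The lists cover catecholamine synthesis, transport, breakdown and D2-type receptors, catecholaminergic and diencephalic transcription factors, noradrenergic and sympathetic genes, serotonergic and histaminergic genes, pan-neuronal genes, glutamatergic and GABAergic transmission, neuropeptides, ion channels and axon guidance receptors, neural progenitors and glia, cell cycle, muscle, erythroid cells, leukocytes and endothelium, epidermis and periderm, neural crest and pigment cells, retina and lens, endoderm with liver, pancreas, gut and yolk, cartilage with connective tissue and notochord, stress and immediate early genes, Parkinson disease gene orthologues, cytoplasmic ribosomal proteins and mitochondrially encoded genes. The genes named are, per experiment, the 6 highest and 4 lowest ratios among named genes with at least 20 CPM and 50 reads in the larger library, the members of the catecholamine list, up to 4 members of each list with the largest ratios at the same minimum, and at 24 h the listed transcription factors with at least 20 CPM in either GFP-positive library. The rule's other parts, which rest on a fit across experiments, were not used, and its list part was applied per experiment instead of to that fit. There is 1 result under the rule that was left out and is not reported here. Names come from the tables for 25939 features and otherwise from the 2 reference name tables. Added lists for hatching gland, heart muscle, pancreatic islet hormones, germ cells and notochord were written after the values were seen.

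The planned edgeR fits across the 4 mRNA-seq experiments, across the 2 NanoCAGE experiments and for the difference between the th:Gal4 and th:GFP lines, with their gene set tests, are left out, as is the planned limma test on the log2 ratios of the pairs. This was a choice: outside the vmat2 table all reads derive from the authors' comparison columns, which were given no replicate number, and fits made while the tables were explored tied columns to libraries by their order and were discarded. The alternatives run were a prior count of 0.5, library size scaling, a minimum of 20 CPM and 50 reads, and, added after seeing the data, unique exon reads in the vmat2 table.

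Exon reads behind the comparisons ran from 495373 to 1367216 in the NanoCAGE libraries, from 21326333 to 27682819 in the th:Gal4 libraries and from 52869 to 79653 in the th:GFP libraries. The floor of 3 reads is 0.132 CPM in the 36 h GFP-positive library and 56.7 CPM in the 72 h GFP-positive library. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Of the reads in the vmat2 experiment, 52.4% of the GFP-negative and 69.8% of the GFP-positive exon reads were unique, so reads shared between near-identical genes, such as globin, tubulin and hatching enzyme copies, leave the split among the copies uncertain.

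The steps were tested on simulated pairs drawn from the real means and library sizes. With 200 genes changed 8-fold in the simulated vmat2 comparison, 96.0% of them came out at least 4-fold changed among 5671 genes, and 1 unchanged gene did. In the simulated 48 h comparison these were 99.0% and 0 of 9476 genes. In the simulated 72 h comparison, with 40 genes changed 8-fold among 394, all 40 came out at least 4-fold changed, and the unchanged genes had a median log2 ratio of -0.35, so scaling at that depth left part of a composition shift in place. Of 100 lists of 20 unchanged genes, 5, 7 and 0 were set apart in the 3 simulated comparisons. The simulated libraries differ by counting error alone, with as many genes raised as lowered, whereas the real vmat2 pair had 708 higher and 219 lower. The otpb pair was not simulated. So the simulation checks the steps only, and does not show that real 4-fold counts or lists set apart would recur in other libraries. The simulation was itself changed after its first outcomes were seen: the number of changed genes at 72 h was lowered, because with about 1 gene in 2 changed the scaling left a larger shift, and 100 unchanged lists replaced a single one. No setting of the real comparisons was altered by it. Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.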

Results

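RNA was profiled in cells sorted by green fluorescence from whole zebrafish at 5 ages, with 4 transgenic strategies meant to label catecholaminergic cells. The vmat2 enhancer trap line, named for the vesicular monoamine transporter, was used at 24 h because it then marks neurons of the posterior tuberculum (a ventral diencephalic dopaminergic region) and of the locus coeruleus, the noradrenergic nucleus of the hindbrain. The otpb line, which carries an enhancer of a diencephalic homeobox gene, was also used at 24 h and marks dopaminergic cells of the ventral diencephalon and some preoptic cells. A th:Gal4 driver with a GFP responder was used at 36 and 48 h, and a th:GFP bacterial artificial chromosome at 72 and 96 h, th being the gene for tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis. In each experiment 1 GFP-positive library stood against 1 GFP-negative library. There are no replicates: every interval covers counting error only, and a difference describes these libraries.

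Exon reads in the GFP-negative and GFP-positive library were 1173909 and 918362 for vmat2, 1367216 and 495373 for otpb, 21326333 and 22779177 at 36 h, 27682819 and 25011503 at 48 h, 79653 and 52869 at 72 h, and 63631 and 70510 at 96 h. The 4 features with most reads took between 34.4% and 56.8% of the NanoCAGE reads, against 4.5% to 14.8% in the th:Gal4 libraries and 6.7% to 11.5% in the th:GFP libraries. Assay, line and age change together between the 3 sets, so levels are compared within a pair. All reads outside the vmat2 experiment are those recovered from the authors' deposited table of comparisons, and directions there follow the convention of the vmat2 table.

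The first question was whether the sorted cells carried catecholamine pathway transcripts. Reads of th (chromosome 25, 24778671 to 24797839 on Zv9) were more frequent in the GFP-positive library in all 6 experiments, although otpb had 1 read against 0. In the vmat2 experiment there were 15 reads against 0, at least 4.13-fold higher. At 36 h there were 44 against 18 (log2 ratio 1.80, counting interval 1.12 to 2.82) and at 48 h 272 against 31 (3.06, interval 2.61 to 3.73). At 72 h 13 reads stood against 0, at least 5.58-fold higher, and at 96 h 10 against 0, at least 2.81-fold higher. These folds against the floor leave out the counting error of the GFP-positive reads. The lowest exact lower bound of th from 36 to 96 h was a log2 ratio of 0.92. In CPM the 48 h GFP-positive library held 10.9 for th, so th was a rare transcript there. The gene ddc (chromosome 16, 9598874 to 9643081), which encodes the decarboxylase that makes dopamine from L-DOPA, had 107 reads against 24 at 36 h (log2 ratio 2.69, interval 2.16 to 3.51) and 241 against 57 at 48 h (2.05, interval 1.67 to 2.53).

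The noradrenergic enzyme gene dbh (dopamine beta-hydroxylase; chromosome 10, 10530157 to 10573014) was higher in the GFP-positive library at 36 h, with 204 reads against 4 (log2 ratio 5.64, interval 4.94 to 8.21). At 48 h it had 49 reads against 34 and an interval that includes 0 (-0.12 to 1.21). It had 18 reads against 0 at 72 h, at least 7.73-fold higher, and 11 against 0 at 96 h, at least 3.09-fold higher. GCH1 (chromosome 17, 14962921 to 14990381), for GTP cyclohydrolase, the entry enzyme to the tetrahydrobiopterin cofactor of tyrosine hydroxylase, had 18 reads against 1 at 72 h (log2 ratio 2.97, interval 1.87 to 9.92) and 12 against 0 at 96 h, at least 3.37-fold higher. At 36 h GCH1 was lower by the deposited RPKM (1.14 against 2.13), whose library size scaling lowers nearly all 36 h ratios. The vesicular transporter gene slc18a2 had 9 reads against 0 in the vmat2 experiment, at least 2.48-fold higher, 22 against 4 at 48 h, and 0 against 8 at 36 h. Summed over the list, catecholamine genes had 79 reads against 6 at 72 h (log2 ratio 4.08, interval 2.90 to 5.57) and 48 against 3 at 96 h (3.75, interval 2.12 to 6.08). The same sums went the other way at 24 h, with 68 against 110 for vmat2 (-0.97, interval -1.43 to -0.52) and 30 against 110 for otpb (-0.84, interval -1.48 to -0.25), where gch2 gave 62 and 57 of the GFP-negative reads. With library size scaling the 24 h ratios were -0.34 and -0.41, and their intervals, moved by the same amounts, would include 0. At 36 h the sum was 3952 against 5139, with a log2 ratio of 0.27 that was -0.47 with library size scaling.

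**Figure D1:**
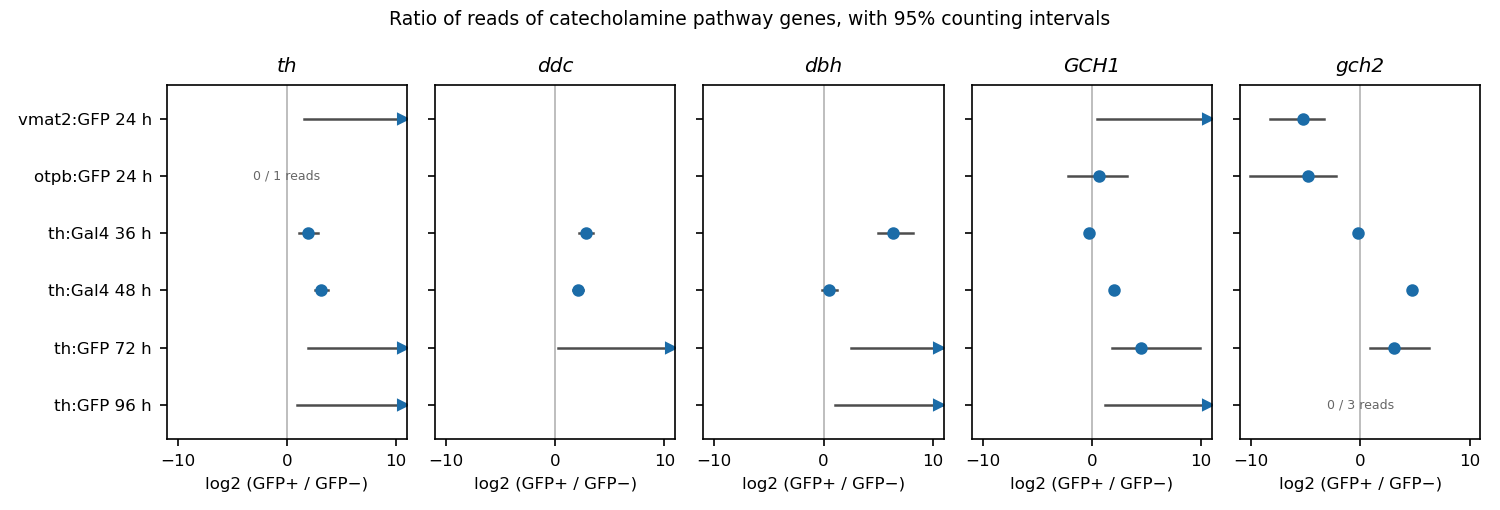
Log2 ratio of reads (GFP-positive over GFP-negative, TMM-scaled) of 5 catecholamine pathway genes in each of the 6 experiments. Points are ratios of reads with no prior count, lines are exact 95% counting intervals, arrows mark genes with 0 reads in the GFP-negative library, small text gives GFP-negative and GFP-positive reads where fewer than 4 were found in all, and an empty row has no reads or equal levels. The th intervals drawn lie above 0, with none drawn for otpb, which has 1 th read and an interval that includes 0, while gch2 lies below 0 in both 24 h experiments and above 0 at 48 h and 72 h.

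In the vmat2 experiment at 24 h the GFP-positive library was marked by genes of blood and vessel cells. All 32 measured members of the leukocyte and endothelial list were at least 2-fold higher and 31 were at least 4-fold higher, with a median log2 ratio of 3.79, above all 10000 matched random lists. Each of the 32 passed the minimum through its GFP-positive reads, so these shares depend partly on the minimum. Without it, the 43 matched members had 6344 reads against 278 (log2 ratio 4.24, interval 4.06 to 4.41). With the list's 9 members that had 0 GFP-negative reads put at the floor of 3 reads, the median was 3.61 and the 31 stayed at least 4-fold higher. Coro1a, an actin regulator of leukocytes, had 305 reads against 0 and was at least 83.9-fold higher. Spi1, the transcription factor of the myeloid lineage, had 296 against 0, at least 81.4-fold higher, and ptprc, the leukocyte phosphatase CD45, had 98 against 0, at least 27.0-fold higher. Lcp1, for the leukocyte actin bundler L-plastin, had 472 against 3 (log2 ratio 6.35, interval 5.46 to 9.30). The receptor gene csf1ra of macrophages and pigment cells had 60 against 1 (4.19, interval 3.10 to 10.96). The list held 0.691% of GFP-positive and 0.0237% of GFP-negative reads.

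Cardiac muscle genes were also higher in that library, while the median of the muscle list was -1.47 over 28 members. The ventricular myosin vmhc had 1202 reads against 7 (log2 ratio 6.82, interval 6.10 to 8.46), the atrial myosin myh6 206 against 2 (5.50, interval 4.54 to 9.46) and the cardiac light chain myl7 453 against 9 (5.12, interval 4.44 to 6.51). The smooth muscle myosin myh11a had 441 against 1 (7.03, interval 6.02 to 13.82). The extracellular matrix gene hapln1b had 246 against 4 (5.14, interval 4.29 to 7.55), in a connective tissue list whose median was -0.96. Epidermis and periderm genes had a median of 1.21, with 10 of 32 members at least 4-fold higher, the immediate early gene egr1 had 137 reads against 11 in a stress list with a median of 0.53, and mitochondrially encoded genes had a median of 0.46.

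Neural progenitor and glia genes had a median of -1.0 over 27 members in the vmat2 experiment, set apart on the low side, and 13 members were at least 2-fold lower. With library size scaling the median was -0.40. The reads summed over the list had a log2 ratio of -0.59 (interval -0.68 to -0.51), or 0.04 with library size scaling, so the direction of the sum depends on the scaling. Plp1a had 18 reads against 149, the early neural gene sox19a 19 against 135, and the Notch ligand gene dld 14 against 85. The somite gene tbx24 had 2 against 73 (log2 ratio -4.43) and gch2, a GTP cyclohydrolase gene of pigment cell precursors, 2 against 62 (-4.21, interval -8.31 to -3.32). Pan-neuronal genes had a median of 0.39, which was not set apart (80.3% of random lists lay below it), with atp1a3a higher (66 against 11) and stmn1b lower (20 against 78). The direction of that list depends on the setting: its median was -0.90 at the stricter minimum, and the reads summed over it had a log2 ratio of -0.60 (interval -0.68 to -0.52), or 0.03 with library size scaling. Retina and lens genes (median -2.07), pigment and neural crest genes (-1.15) and ribosomal protein genes (-0.98) were set apart on the low side. The cell cycle list was too (-0.42), but its median was 0.21 with library size scaling. In all, 708 of 6303 genes were at least 4-fold higher and 219 at least 4-fold lower. With library size scaling these were 1109 and 101, and at the stricter minimum 306 and 71.

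In the otpb experiment at 24 h the leading genes of the GFP-positive library belonged to the hatching gland, the notochord and the epidermis. Ctsl1b, a cathepsin of the hatching gland, had 504 reads against 40 (log2 ratio 4.60, interval 4.22 to 5.19), and the hatching enzyme genes he1b and he1a had 180 against 50 and 156 against 56. Cmn (calymmin), a gene of the notochord sheath, had 441 against 89 (3.30, interval 3.01 to 3.69), and emilin3a 115 against 20 (3.39, interval 2.86 to 4.32). The Hox gene hoxc13a had 71 against 0, at least 48.4-fold higher. That fold rests on its absence from 1 library. In the vmat2 experiment, at the same age and with the same assay, hoxc13a went the other way, with an RPKM of 8.64 against 17.07. Epidermis and periderm genes had a median of 0.58 over 30 members, and pan-neuronal genes of 0.31 over 17, both set apart on the high side. In the latter stmn1b had 83 reads against 18 (3.06, interval 2.49 to 4.06), the opposite direction to the vmat2 experiment. Of the 30 epidermis and periderm members, 11 were at least 2-fold higher and 6 at least 2-fold lower. The hatching gland genes he1a, he1b and ctsl1b are among the 5 members of that list that were at least 4-fold higher. The matrix genes col11a2 (183 against 77), hapln1a (546 against 309) and col9a1 (322 against 189) were higher, in a connective tissue list that was set apart on the high side of its matched lists. Its median was 0.00, or 0.42 with library size scaling and 0.92 at the stricter minimum.

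Vessel genes were lower in the otpb GFP-positive library. The 9 measured members of the leukocyte and endothelial list had a median of -1.81, with tie1 at 2 reads against 69, the VEGF receptor gene kdrl at 22 against 185 and stab2 at 32 against 240. Mitochondrially encoded genes (median -0.97), endoderm, liver and yolk genes (-1.35, with the apolipoprotein gene apobl at 54 reads against 539) and muscle genes (-0.70) were also set apart on the low side. Ribosomal protein genes had a median of -0.38, and of 0.05 with library size scaling. The heme synthesis gene cpox had 2 reads against 99. In all, 123 of 4666 genes were at least 4-fold higher and 344 at least 4-fold lower, or 206 and 251 with library size scaling. At the stricter minimum these were 37 and 61. The GFP-negative library was the deeper one (1367216 against 495373 reads), so the minimum admits lower genes more readily and the balance of these counts partly reflects depth. With genes at 0 reads in 1 library put at their bound, 298 were at least 4-fold lower.

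Across the 2 NanoCAGE experiments the log2 ratios did not go together over genes (Pearson r = -0.03, Spearman rho = -0.00 over 4068 genes, which are not independent replicates; 1 of 15 pairs of experiments compared). Still, 21 genes were at least 4-fold higher in both, where independent sets would share 4.52, and 10 were at least 4-fold lower in both, where 5.55 would be shared. At the stricter minimum r was 0.055, with an interval of 0.0073 to 0.102. Of the listed transcription factors, arnt2, which encodes a partner of the hypothalamic regulator Sim1, had 21 reads against 10 in the otpb experiment (log2 ratio 1.85, interval 0.95 to 3.35) and 46 against 34 in the vmat2 experiment, with an interval that includes 0 (-0.51 to 0.84). Isl1 had 32 against 24 for otpb (1.35, interval 0.64 to 2.27). Foxa3 is also in the endoderm list and in the added hatching gland list. It was higher in both experiments, with 30 against 3 for vmat2 (2.47, interval 1.36 to 5.40) and 12 against 8 for otpb (1.35, interval 0.20 to 3.11). Sox11b was lower in both, with 67 against 170 (-1.59) and 21 against 111 (-1.32), as was meis1, with 87 against 166 (-1.19) and 57 against 177 (-0.59), and ebf3 was higher for vmat2 (42 against 15) and lower for otpb (3 against 43). The transcription factor list had a median of -1.38 for vmat2, set apart, and of -0.60 for otpb, not set apart.

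At 36 h the th:Gal4 GFP-positive library was rich in hatching gland, heart and periderm transcripts. The hatching enzyme genes he1b and he1a had 67242 reads against 86 (log2 ratio 10.22, interval 9.95 to 10.58) and 120005 against 228 (9.67, interval 9.50 to 9.88), and ctsl1b 76621 against 159 (9.54, interval 9.34 to 9.79). Among heart genes, vmhc had 6018 against 8 (9.82, interval 9.22 to 11.42), cmlc1 12076 against 38, myl7 9623 against 37 and the troponin gene tnnt2a 3319 against 15. Of 48 measured epidermis and periderm genes, 41 were at least 2-fold and 32 at least 4-fold higher, with a median of 3.17, and the list took 6.66% of GFP-positive and 0.665% of GFP-negative reads. That list also holds he1a, he1b and ctsl1b. Icn2, an ictacalcin of the skin, had 82941 reads against 1072.

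Several pancreatic islet hormone genes were higher at 36 h as well: ins (insulin) had 1270 reads against 68 (log2 ratio 4.82, interval 4.52 to 5.25), sst2, a somatostatin gene, 3933 against 89 (6.08, interval 5.81 to 6.43) and the glucagon gene gcgb 628 against 26 (5.12, interval 4.68 to 5.87). Another somatostatin gene, sst1.1, had 116 against 119, and its log2 ratio of 0.60 was -0.13 with library size scaling. The endoderm list that holds them had a median of 1.32. Ribosomal protein genes had a median of 1.62, with 55 of 67 at least 2-fold higher, and took 33.7% of GFP-positive and 20.3% of GFP-negative reads. The muscle list was set apart on the high side of its matched lists (99.5%), with a median of 0.25 that was -0.49 with library size scaling. Pigment cell genes were not set apart as a list (median 0.05, and -0.69 with library size scaling), though dct, an enzyme of melanin synthesis, had 1628 reads against 592.

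Erythroid genes were lower at 36 h, 17 of 28 by at least 4-fold, with a median of -2.19. Alas2, the heme synthesis enzyme of red cells, had 80 reads against 3520 (log2 ratio -4.78, interval -5.15 to -4.49), slc4a1, the red cell anion exchanger, 290 against 9235, and epb41 33 against 1181. Smaller shifts to the GFP-negative side were set apart for leukocyte and endothelial genes (-0.83), GABAergic and glutamatergic genes (-0.75), the transcription factor list (-0.52), cell cycle genes (-0.45), neural progenitor and glia genes (-0.37), pan-neuronal genes (-0.36) and stress genes (-0.33). The progenitor gene her4.2 had 18 reads against 470, ascl1b, a proneural gene, 219 against 1035, and the GABA transporter gene slc32a1 236 against 840. The catecholamine list had a median of 0.98 over 6 measured genes, set apart on the high side, led by dbh and by qdpra (140 against 50). That median was 0.24 with library size scaling and 0.62 at the stricter minimum. Both th and ddc were under 5 CPM at 36 h and are not among these genes. Pcbd1 had 606 against 616, and its log2 ratio of 0.62 was -0.12 with library size scaling. In all, 549 of 9935 genes were at least 4-fold higher and 171 at least 4-fold lower. With library size scaling the balance turned, to 338 and 591.

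At 48 h the th:Gal4 GFP-positive library was marked by pigment cell genes, a list that was not set apart at 36 h; the difference between the ages was not tested. Of 34 measured members of the pigment and neural crest list, 26 were at least 4-fold higher, with a median of 4.24. The melanin synthesis genes dct, tyrp1b and tyr had 64275 reads against 1333, 96738 against 2120 (log2 ratio 5.52) and 782 against 15, and silva, for a melanosome matrix protein, 65072 against 1441. Several tetrahydrobiopterin genes, which pigment cells use for pteridines and catecholamine cells as cofactor, were higher too: gch2 (chromosome 12, 26612194 to 26618916) had 106457 against 4147 (4.69, interval 4.65 to 4.74), PTS 193 against 11, qdpra 563 against 44 and pcbd1 4450 against 714. The paralogue of qdpra, qdprb1, had 315 against 366, with an interval that includes 0 (-0.43 to 0.02). The catecholamine list, which shares them, had a median of 2.65 over 11 members, of which 8 were at least 4-fold higher. Its receptor gene drd3 had 385 reads against 8 (5.28, interval 4.61 to 6.82), mao, for monoamine oxidase, 345 against 122, and comtb 152 against 30.

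Epidermis and periderm genes stayed on the GFP-positive side at 48 h, with a median of 3.03, 36 of 54 members at least 4-fold higher, and a log2 ratio of 3.61 for the reads summed over the list, which took 0.817% of GFP-negative reads. Foxi3b, a regulator of skin ionocytes, had 579 reads against 13 (log2 ratio 5.29, interval 4.70 to 6.41), and atp1a1a.2, a sodium pump subunit gene, 76262 against 1210. Muscle genes had a median of 1.96 over 48 members, with the slow muscle myosin smyhc1 at 7361 against 85 (6.41, interval 6.14 to 6.77). The germ cell genes nanos and vasa had 3475 against 12 (7.97, interval 7.38 to 9.14) and 661 against 5 (6.57, interval 5.83 to 8.69). The appetite neuropeptide gene agrp had 1511 against 50 (4.87, interval 4.52 to 5.36), and the glial gene s100b 767 against 35. Mitochondrially encoded genes (0.58) and stress genes (0.34) were set apart on the high side.

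Red cell genes were lower at 48 h, 24 of 29 by at least 4-fold, with a median of -3.31. The globin genes hbbe1.1 and hbae3 had 56857 reads against 1158072 (log2 ratio -4.34) and 54848 against 968200 (-4.13), and the list took 9.97% of GFP-negative against 0.633% of GFP-positive reads. The glucagon gene gcgb, which was higher at 36 h, had 1 read against 571 (-7.57, interval -14.45 to -6.66). Retina and lens genes had a median of -1.01. The pan-neuronal list (-0.69), neural progenitors and glia (-0.94), the transcription factors (-0.96), glutamatergic and GABAergic genes (-0.87), ion channels and guidance receptors (-0.64), noradrenergic genes (-0.67), neuropeptides (-0.47, but 0.035 at the stricter minimum) and the cell cycle (-0.75) were all set apart on the low side. No pan-neuronal gene was 4-fold changed in either direction, and elavl3, a marker of young neurons, had 8415 reads against 19994. In all, 924 of 10030 genes were at least 4-fold higher and 122 at least 4-fold lower.

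Over the 9093 genes considered at both ages, the th:Gal4 ratios at 36 and 48 h went together (Pearson r = 0.65, Spearman rho = 0.41). Of these, 376 were at least 4-fold higher at both ages, where independent sets would share 31.3, and 42 were at least 4-fold lower at both, where 1.61 would be shared. Genes are not independent replicates, and the pairs come from the same line and protocol.

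**Figure D2:**
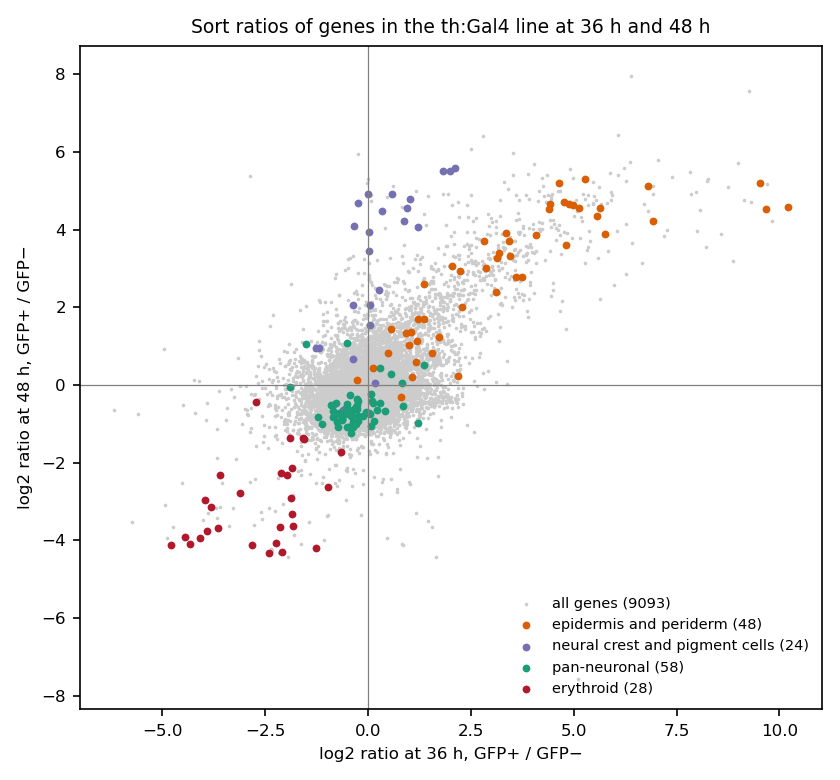
Log2 ratio (GFP-positive over GFP-negative) of each of 9093 genes in the th:Gal4 line at 36 h (horizontal axis) and 48 h (vertical axis), 1 library per group. Each point is a gene, and 4 gene lists are coloured: epidermis and periderm genes lie high and erythroid genes low at both ages, pan-neuronal genes lie near or below 0, and pigment genes are high at 48 h but mostly near 0 at 36 h.

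At 72 h the th:GFP GFP-positive library held more neuronal and fewer skin, muscle and connective tissue transcripts. Pan-neuronal genes had a median of 0.80 over 11 members, above 99.9% of random lists, and sncb, for beta-synuclein, had 68 reads against 37 (log2 ratio 1.19, interval 0.64 to 1.86). Rgs5a, a regulator of G protein signalling, had 57 against 7 (3.03, interval 2.26 to 4.77). Embryonic globins were higher, with hbbe1.1 at 326 against 93 (2.15, interval 1.84 to 2.52) and hbae3 at 315 against 118, and the 3 measured erythroid genes had a median of 1.76. Summed over the noradrenergic list there were 76 reads against 34 (1.53, interval 0.92 to 2.15). That list shares dbh with the catecholamine list, so the dbh reads given earlier are part of this sum. Mitochondrially encoded genes had a median of 0.25.

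All 16 measured epidermis and periderm genes were at least 2-fold lower at 72 h, with a median of -3.07, or -2.83 with the 2 members that had 0 GFP-positive reads at their bound, led by krt5 at 1 read against 59 (log2 ratio -4.11, interval -10.85 to -2.98) and the actinodin gene and2 of the fin fold at 2 against 53. All 14 muscle genes were at least 2-fold lower (median -2.53), with actc1b at 21 against 204, and 6 connective tissue genes had a median of -2.70, with the collagen gene col1a1a at 19 against 173. In all, 8 of 415 genes were at least 4-fold higher and 40 at least 4-fold lower, or 2 and 24 at the stricter minimum. The GFP-negative library was the deeper one (79653 against 52869 reads), so the minimum admits lower genes more readily. Only 415 genes reached the minimum at this depth, so a gene outside these 415 was below the minimum and cannot be called unchanged.

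Among the 456 genes that reached the minimum at 96 h, the th:GFP sort differences were small beside those of the other experiments. At this depth rare genes are not among them. No catecholamine gene reached the minimum, although the reads summed over that list were 48 against 3. Muscle genes were lower, with a median of -1.63 and all 13 members at least 2-fold lower, among them the parvalbumin gene pvalb1 at 31 reads against 112 (log2 ratio -2.02, interval -2.72 to -1.51) and actc1b at 38 against 119. Retina and lens genes had a median of 0.34 over 14 members, set apart on the high side. Among named genes at the stricter minimum, slc25a43, a mitochondrial carrier gene, was highest at 140 against 41 (1.49, interval 1.01 to 2.07). Next came the brain aldolase gene aldocb at 57 against 22. GCH1 and dbh, with fewer reads, were not part of this ranking. Pan-neuronal genes had a median of 0.27 that was not set apart (95.3%) and was -0.18 at the stricter minimum. Connective tissue (-0.85), epidermis and periderm (-0.43, but 0.0078 at the stricter minimum) and ribosomal protein genes (-0.30) were set apart on the low side. In all, 0 of 456 genes were at least 4-fold higher and 4 at least 4-fold lower. The 72 h and 96 h ratios correlated over 347 genes with r = 0.34 (rho = 0.20). A value of that size is not particular to this line: vmat2 with th:Gal4 at 48 h gave r = 0.34 (rho = 0.36) over 4979 genes. Between 48 h and 72 h r was -0.34 over 410 genes.

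Seen over all experiments, cell cycle genes had a median below 0 in 6 of 6, though library size scaling put it above 0 for vmat2, otpb and 96 h. A sign against 0 says little here, since the median over all considered genes was itself -0.44 for otpb and -0.36 at 72 h. Among matched lists the cell cycle list was not set apart for otpb, 72 h or 96 h (27.6%, 19.2% and 51.5% of random lists lay below it). The transcription factor list had a median below 0 in 6 of 6 with either scaling, with only 1 and 2 measured members at 72 and 96 h. For otpb it was not set apart (37.8% of random lists lay below it). The reads summed over the transcription factor list went the other way at 72 h, with 151 against 142 (log2 ratio 0.45, interval 0.11 to 0.79), and gave intervals that include 0 for otpb (-0.12 to 0.15) and at 96 h (-0.53 to 0.05). With library size scaling the otpb sum had a log2 ratio of 0.45, on the GFP-positive side. Epidermis and periderm genes were above 0 in the 4 experiments up to 48 h and below 0 in the 2 later ones, except at 96 h with the stricter minimum. Serotonergic and histaminergic genes had at least 3 measured members only at 36 h, where their median of -0.64 was not set apart, and the Parkinson disease gene orthologues were not set apart in any experiment that measured 3 of them (medians of 0.03, -0.81, -0.22 and 0.09 from 24 to 48 h). Of 99 medians with at least 3 members, 60 were set apart.

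**Figure D3:**
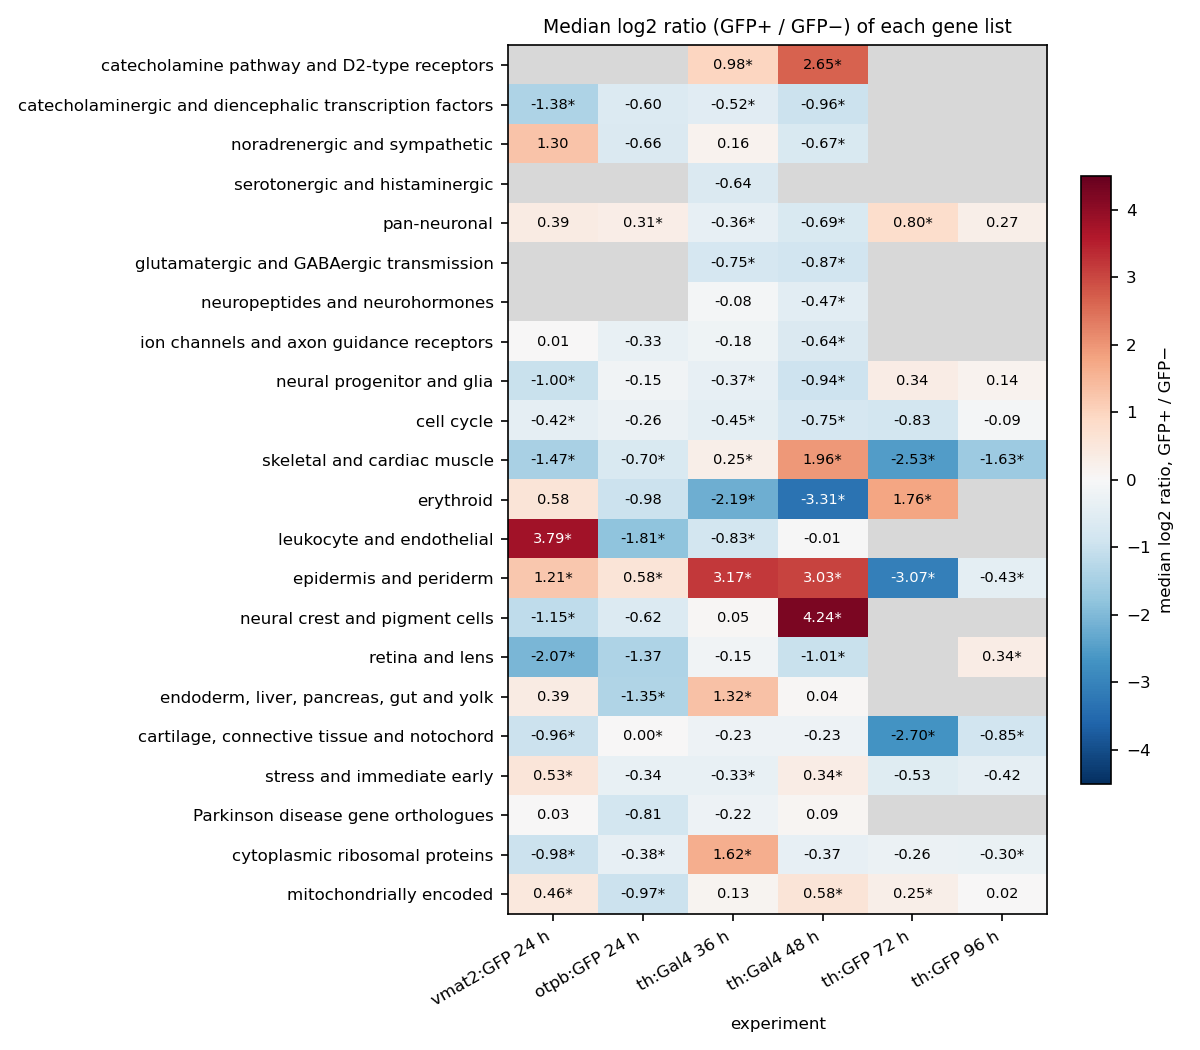
Median log2 ratio (GFP-positive over GFP-negative, TMM-scaled) of each of 22 gene lists (rows) in each of 6 experiments (columns), coloured from blue (lower) to red (higher). A star marks a median outside the central 95% of 10000 matched random lists, and grey cells had fewer than 3 measured members. Leukocyte and endothelial genes stand out for vmat2 (3.79), epidermis at 36 h and 48 h (3.17 and 3.03), and pigment cells at 48 h (4.24); the lists whose direction turns with library size scaling include cell cycle for vmat2, ribosomal proteins for otpb and muscle at 36 h.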

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

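All tests of explanations in this part were chosen after the values they use had been seen, and the 3 patterns weighed were picked from 22 lists in 6 experiments. The differences between lines given first were not tested.

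Of the lists measured in all 4 mRNA-seq experiments, 4 went one way at both th:Gal4 ages and the other way at both th:GFP ages. Epidermis and periderm genes had medians of 3.17 at 36 h and 3.03 at 48 h, against -3.07 at 72 h and -0.43 at 96 h. Muscle genes had medians of 0.25 and 1.96 against -2.53 and -1.63, but with library size scaling, which lowers nearly all 36 h ratios, the 36 h median was -0.49, so its sign there depends on the scaling. That list was still on the high side of its matched lists at 36 h (99.5%). Pan-neuronal genes had medians of -0.36 and -0.69 against 0.80 and 0.27, and neural progenitor and glia genes of -0.37 and -0.94 against 0.34 and 0.14, the last 2 from 3 and 4 genes. The signs of these 3 remaining lists were the same with library size scaling. At the stricter minimum the 96 h medians were 0.0078 for epidermis and periderm and -0.18 for pan-neuronal genes, so for both the contrast is lost at 96 h. Line, age and depth all differ between the pairs of experiments, so the contrast cannot be put down to any one of them.

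For the epidermal contrast, a comparison reversed in some tables would put th, on which the lines are built, on the GFP-negative side there. The lowest lower bound of the th interval over the 4 experiments was 0.92, above 0, which argues against a reversal. The choice between the 2 scalings does not account for it. With library size scaling the lower of the 2 th:Gal4 medians was still 2.43, and the th:GFP medians were -2.91 at 72 h and -0.34 at 96 h. That change of scaling moves the 36 h ratios by a median of -0.74, too little to turn the 36 h median. Epidermal cells in the GFP-positive sort at 36 and 48 h stay a possible explanation that could not be decided: at the age with the lower share 81.5% of measured members were at least 2-fold higher, but this is the list in which the pattern was seen, so the share restates it. The keratin gene krt4 was the feature with most reads in both GFP-positive libraries. The list also holds he1a, he1b and ctsl1b of the hatching gland. The sort for GFP would remove non-fluorescent skin cells, and whether such cells expressed the transgene, fluoresced on their own or were carried along by the sort stays open, and age and line remain as untested biological explanations.

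For the catecholamine list at 48 h, pigment cells in the GFP-positive sort are a candidate source: 75.8% of the 33 measured pigment genes outside the catecholamine list were at least 4-fold higher, with dct at 64275 reads and tyrp1b at 96738. The lists share gch2, which is left out of that share. The bound for the test was set with the values known, so it does not count as independent evidence. The lower bounds of th and ddc at 48 h were both above 0, the lower being 1.67 for ddc. The line is built on th, so a higher th was largely set by the sort and weighs little here. The ddc value argues only against tetrahydrobiopterin genes of pigment cells as the whole of the list's shift. By reads, most of the list's sum of 116670 against 6487 came from gch2. Pigment cells that scatter or emit light in the sort, and a real change of the labelled population between 36 and 48 h, both stay open.

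For the blood and vessel genes in the vmat2 experiment, the 4 features that hold most reads might have distorted the library totals. Leaving them out moved every ratio by the same -0.58, and the leukocyte and endothelial median went from 4.18 with library size scaling to 3.60. The 4 features therefore account for little of this median. A constant shift of that size could not have removed it, so the comparison shows no more than that. Blood and vessel cells in the GFP-positive sort, which the GFP sort would remove if they did not fluoresce, stay a possible explanation that could not be decided: 96.9% of the 32 measured members were at least 4-fold higher, led by coro1a and spi1, but the pattern was seen in this same list. Each of these members also passed the minimum through its GFP-positive reads. The list shares csf1ra with the pigment list and cebpb with the stress list. The otpb experiment, at the same age and with the same assay, had a median of -1.81 for this list. That median rests on 9 members, and the deeper otpb GFP-negative library lets lower genes pass the minimum more readily. Coro1a, spi1 and lcp1 were below the minimum there, so the median does not cover them. Without the minimum, the list had 230 reads against 1301 for otpb (log2 ratio -1.47, interval -1.68 to -1.27), so the assay alone does not give the vmat2 shift of the list as a whole. Expression of the trap line in such cells and their carry-over in the sort were not separated.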

How the results depend on the processing

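The alternatives were fixed before the data were examined, except unique exon reads in the vmat2 experiment, chosen after seeing the data, which kept both 4-fold counts within 1.5 times (657 higher and 174 lower). The fits across experiments and their alternatives (other size factors, filters, tools, blocks, all 6 experiments, leaving out an experiment, gene set tests with either correlation) were left out and none is reported, because the authors' comparison values were given no replicate number. The groups share only 1 replicate number, so none served as a block, and a test over the experiments as pairs was left out by the same choice. Of the 38 values of 4-fold counts under an alternative, 19 stayed within 1.5 times of the reported count. Of 30 correlations 22 stayed inside the reported interval, and at the stricter minimum vmat2 with otpb and 48 h with 96 h, both with intervals that include 0, changed sign to 0.055 and 0.066. A list median was taken as kept within 0.1, a tolerance set after seeing the data. Of 179 values for the 60 medians that were set apart 96 were kept, 78 moved and 5 reversed. Of 682 ratios of genes named by rank or as catecholamine genes 557 stayed inside their counting interval, 122 moved and 3 reversed. Over all list medians with at least 3 members, 12 of 99 changed sign with library size scaling, 8 of 95 at the stricter minimum and 0 of 99 with a prior count of 0.5.

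With library size scaling the counts at least 4-fold higher and lower moved to 1109 and 101 for vmat2, 338 and 591 at 36 h, 206 higher for otpb and 2 lower at 96 h. With the minimum of 20 CPM and 50 reads, which considers fewer genes, they were 306 and 71 for vmat2, 37 and 61 for otpb, 275 and 37 at 36 h, 525 and 78 at 48 h, 2 and 24 at 72 h, and 1 lower at 96 h. With a prior count of 0.5 the 96 h counts were 1 and 7. At the stricter minimum the correlation of vmat2 with otpb was 0.055 and that of 36 h with 48 h was 0.70; the cause was not tested.

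With library size scaling, which moves the ratios of a pair in the same direction, the cell cycle median of vmat2 became 0.21, the ribosomal protein median of otpb 0.049 and the muscle median at 36 h -0.49, and the 36 h ratios of pcbd1, elavl4 and slc17a6b became -0.12, -0.54 and -0.27. At the stricter minimum the neuropeptide median at 48 h was 0.035 and the epidermis and periderm median at 96 h was 0.0078, from fewer members. Depth limits the th:GFP experiments most: 415 and 456 genes were considered there, against 9935 and 10030 in the th:Gal4 experiments.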

Other observations

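The values below come from lists written after the highest genes of the experiments had been seen, so they describe where a tissue's genes were found and test nothing. Heart muscle genes were higher in the GFP-positive library in several experiments. Of 12 measured at 36 h, 10 were at least 4-fold higher, with a median log2 ratio of 7.55. At 48 h these were 9 of 10 with a median of 3.94, and for vmat2 6 of 7 with a median of 3.83. At 36 h the natriuretic peptide gene nppa had 1075 reads against 5 (log2 ratio 7.82, interval 7.17 to 10.02), mybpc3 1268 against 14, and the cardiac transcription factor gene nkx2.5 257 against 22. Its partner genes hand2 (350 against 349) and gata5 (75 against 63) were close to even in reads, and their log2 ratios of 0.65 and 0.87 became -0.09 and 0.15 with library size scaling.

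Hatching gland genes were on the GFP-positive side in the 4 experiments up to 48 h, with medians of 2.47 for vmat2, 1.75 for otpb, 1.88 at 36 h and 1.59 at 48 h. Summed over the list the reads were 280269 against 11118 at 36 h and 129675 against 18148 at 48 h. He1a, he1b and ctsl1b held most of the GFP-positive reads at both ages. At 36 h agr2 (9150 against 3153, log2 ratio 2.18), foxa3 (1.57) and cd63 (1.26) were also higher, while xbp1 and prdm1a, also used elsewhere in the embryo, had log2 ratios of 0.29 and 0.44, which became -0.45 and -0.30 with library size scaling. He1a, he1b and ctsl1b are also in the epidermis and periderm list, as heart genes are in the muscle list.

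In the th:Gal4 experiments germ cell genes were found mostly in the GFP-positive libraries. At 48 h 5743 reads stood against 65, all 5 measured members were at least 4-fold higher, and the median was 6.57. Besides nanos and vasa these were dnd at 295 against 2 (log2 ratio 6.22, interval 5.35 to 10.27), tdrd7 at 493 against 3 and ca15b at 460 against 3. At 36 h 663 reads stood against 59, of which nanos gave 448 against 6. The other experiments had between 0 and 26 reads of the list in any library, and their lower depth does not show that these transcripts were rarer there.

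Most islet hormone genes changed side between the 2 th:Gal4 ages. At 36 h the 5 genes had 6029 reads against 302, and at 48 h 299 against 1081. Gcgb went from 628 against 26 to 1 against 571, sst2 from 3933 against 89 to 5 against 39, and gcga from 82 against 0 to 5 against 24. Sst1.1 went from 116 against 119 to 112 against 383, and its 36 h direction depends on the scaling. Ins stayed on the GFP-positive side, with 176 against 64 at 48 h. The change was not tested.

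Notochord genes were on the GFP-positive side for otpb, with a median of 1.85 over 6 genes, and on the GFP-negative side for vmat2, with a median of -1.99 over 4. Cmn had 441 reads against 89 for otpb and 6 against 59 for vmat2, and shha, a signal of notochord and floor plate, 58 against 29 and 13 against 36.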
